A study of Homo sapiens with 4 samples.

How the data were processed

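The series holds 4 ribosome profiling libraries from HCT116, a human colorectal carcinoma cell line. Ribosome profiling sequences the short mRNA fragments that ribosomes shield from nuclease, so a gene's footprint count reflects both how much of its mRNA is present and how heavily it is translated. The design text of the series names meRIP-seq instead, a method that enriches methylated RNA, while its title, the labels and the protocols give ribosome profiling. Counts on protein-coding genes are read here as footprints on that basis, which the table cannot check. No RNA-seq was used here, so the counts do not separate these parts. Per the labels' protocols, elongating ribosomes were halted with cycloheximide, lysates were digested with RNase A, ribosomal RNA was depleted, fragment ends were repaired with T4 polynucleotide kinase, and small RNA libraries were selected on a gel. The labels put 2 libraries in a wild-type control group, also marked V2, a code they do not explain, and 2 in a TRMT61A knockout group.

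The deposited table gives raw counts for 66740 Ensembl transcripts with a gene symbol each, together with the authors' own comparison. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.6, Bowtie 1.3.0, STAR 2.7.8a and DESeq2 1.30.0 on hg38, with no roles stated. The counting tool, the annotation release and the treatment of reads that fit several transcripts are not given in the sources used here. Per the file headers, the authors' table also holds their DESeq2 output: a baseMean signal (mean of counts scaled by size factors), log2 fold changes with standard errors, a Wald score, and p-values before and after adjustment. Library totals were 1500938 and 1710600 counts for control replicates 1 and 2, and 1482638 and 1591484 for knockout-labelled replicates 1 and 2. A floor of 3 counts corresponds to 2.00, 1.75, 2.02 and 1.89 counts per 1000000 (CPM) in the same order. Intervals and floors cover counting error only, since the reads carry no stated molecular identifiers.

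Some highly expressed genes kept few counts: ACTB had 27, 35, 47 and 42 and GAPDH 24, 17, 18 and 10 in the 4 libraries. Levels of different genes are therefore not compared, and genes with near-identical copies or several overlapping transcripts are uncertain. No row carried the symbol of a mitochondrially encoded gene. Nuclear pseudogene copies of those genes held between 10.8% and 12.8% of each library's counts, so reads could not be assigned to either origin.

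Transcript counts were summed by gene symbol, except 384 Y_RNA and 54 Metazoa_SRP transcripts, family names that were kept per transcript. Of 31636 symbols, 21928 matched the RefSeq gene table of GRCh38.p14, which was used for gene class and, in 1 check, for chromosome. Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. TRMT61A and TRMT6 were kept whatever the filter. Standard errors of log2 fold changes were taken from the F statistic. CPM values are TMM-scaled, with the SD over 2 libraries. Every adjusted p for a gene comes from this edgeR fit unless another tool is named. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 gave Wilson intervals of 95% for shares.

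The test, 24 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The naming rule took TRMT61A and TRMT6; up to 4 members of each list with the smallest p; and the 12 genes with the largest change in each direction among those past the threshold, at or above the median expression, with both knockout-labelled libraries on 1 side of both controls. Single values of some list members are not reported here. The table gives no gene type, so this last part ran over all classes. The same rule limited to protein-coding genes was added after the values were seen.

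Replicates were compared by chi-square over transcripts with at least 20 counts in a pair. For protein-coding transcripts chi-square per degree of freedom was 1.35 between the controls and 1.46 between the knockout-labelled libraries, so both pairs differed by more than sampling noise and counted as 2 each. The labels do not say whether replicates came from separate cultures, so p-values rest on the spread between these libraries, which may be technical. The edgeR fit also pools that spread across genes. Exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333, so no per-gene permutation test was used.

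The procedure was tested on simulated data with 9484 genes: 7.46% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 2 of 99 calls fell on unchanged genes. Every simulated gene had the common dispersion of all classes (coefficient of variation 11.98%), and no weakly expressed gene was changed. Protein-coding genes fitted alone had 3.90%, and snoRNAs varied far more between the controls (chi-square per degree of freedom 542). The rates describe that setting and not each class here. Alternatives were RLE and upper-quartile scaling, no or a stricter count filter (mean of 10), DESeq2 1.42.0, limma-voom, robust empirical Bayes, the replicate number as a block, protein-coding genes only, each library left out, and the authors' adjusted p. Transcripts as features and protein-coding genes without control replicate 2 were added after seeing the data. With a library left out, its group keeps a lone library and the spread comes from the other pair alone. Over all transcripts, chi-square per degree of freedom was 13.9 between the controls and 3.14 between the knockout-labelled libraries. A call lost without a knockout-labelled library therefore does not by itself show that the fold depended on that library. A call kept without a control library rests on the spread of the knockout-labelled pair alone and is not firmer for it. Reading frame, codon occupancy and footprint length need the reads and were not analysed.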

Results

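Ribosome footprints were counted in 4 libraries of HCT116 colorectal carcinoma cells, 2 from wild-type controls and 2 labelled as TRMT61A knockout. TRMT61A is the catalytic subunit of the TRMT6/TRMT61A methyltransferase, which makes 1-methyladenosine (m1A) in tRNA and in some mRNAs. The comparison asks which genes carry more or fewer footprints in knockout-labelled cells, and, from the title of the series, whether genes of MAPK/ERK signalling are among them. Library totals were 1500938 and 1710600 counts in control replicates 1 and 2 and 1482638 and 1591484 in knockout-labelled replicates 1 and 2.

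Protein-coding genes took 64.0% of counts in control replicate 1 (95% Wilson interval 63.9% to 64.0%), 56.9% (56.8% to 57.0%) in control replicate 2, 61.3% (61.2% to 61.4%) in knockout-labelled replicate 1 and 59.9% (59.9% to 60.0%) in knockout-labelled replicate 2. Small nucleolar RNAs (snoRNAs), which guide rRNA modification and are not translated, took 8.12% (8.08% to 8.17%), 19.1% (19.0% to 19.1%), 9.53% (9.48% to 9.57%) and 10.5% (10.5% to 10.6%) in the same order. Control replicate 2 thus stood apart from the other 3 libraries, with SNORD101 alone at 86906 counts against 4684 in control replicate 1. MicroRNAs held 2.95% (2.92% to 2.97%) and 1.718% (1.698% to 1.737%) of the control libraries and 3.29% (3.26% to 3.32%) and 4.17% (4.14% to 4.20%) of the knockout-labelled ones. Spliceosomal small nuclear RNAs held 1.54% (1.52% to 1.56%) and 1.39% (1.38% to 1.41%) in controls against 1.81% (1.79% to 1.83%) and 1.79% (1.77% to 1.81%).

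**Figure D1:**
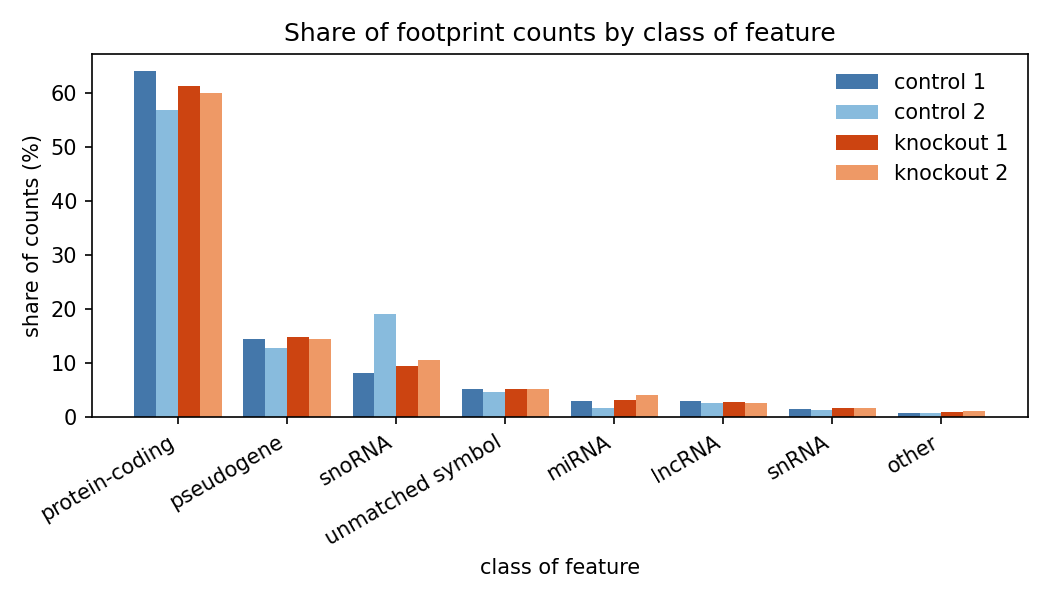
Share of each library's counts (percent, vertical axis) by class of feature, with 1 bar per library, 2 control and 2 knockout-labelled. The snoRNA bar of control replicate 2 reaches 19.1%, against 8.12% to 10.5% in the other 3 libraries.

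TRMT61A footprints were not lower in the libraries labelled knockout. TRMT61A (ENST00000389749) had 3 and 8 counts in the control libraries and 6 and 9 in the knockout-labelled libraries, a rate ratio of 1.42 (95% interval 0.611 to 3.43, exact test of the reads, p = 0.435). The edgeR log2 fold change was 0.41 ± 0.63 (SE), adjusted p = 0.800, and −0.14 without control replicate 1. Its partner TRMT6, the RNA-binding subunit, had 3 and 5 counts in controls and 1 and 2 in knockout-labelled libraries, a rate ratio of 0.392 (0.0669 to 1.63) with edgeR adjusted p = 0.459. A small deletion need not lower a gene's footprints, and the table does not show where in the gene the reads lie, so these counts do not check the label at this depth. Directions below are those of libraries labelled knockout.

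In the knockout-labelled libraries EREG (ENST00000244869), which encodes the EGFR ligand epiregulin, fell from 6590 ± 105 to 4392 ± 23.2 CPM (SD, n = 2 per group), and AREG (ENST00000395748), the ligand amphiregulin, from 709 ± 19.6 to 385 ± 17.9. ATF3, a stress-induced transcription factor, fell from 176 ± 20.2 to 67.9 ± 7.22 CPM. MAP1LC3B, whose product coats autophagosomes, rose from 1878 ± 16.7 to 3738 ± 16.3 CPM, and VEGFA, the angiogenic growth factor, from 45.5 ± 11.5 to 83.1 ± 10.8. Of 9930 genes tested, 381 passed the threshold, 116 higher and 265 lower, of which 22 and 51 changed at least 2-fold. Among 7378 protein-coding genes, 67 were higher and 175 lower. In all, 47.7% of genes had both knockout-labelled libraries on the same side of both controls, where chance gives 33.3% for a single gene. Genes in the same libraries are not independent, so any shared difference between the groups can raise that share. At an unadjusted p under 0.05 there were 1799 genes. The count past the threshold was 124 without knockout-labelled replicate 1, 52 without knockout-labelled replicate 2, 238 with DESeq2, 736 with robust empirical Bayes and 626 when protein-coding genes were fitted alone. That last fit had a biological coefficient of variation of 3.90%, against 11.98% with all classes, and its 626 calls held all 242 protein-coding calls of the fit with all classes. Its edgeR adjusted p for EREG was 3.05e-99, which 2 libraries per group cannot give from 1 gene's own spread. The p-values of that fit thus lean on spread pooled across genes, and its added calls are not firmer. Without a knockout-labelled library the spread came from the control pair alone, so the lower counts there do not show that folds changed.

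In the list of ERK transcriptional output, genes that report ERK activity, 5 of 20 tested genes fell, 0 rose and 15 did not pass (9 lower when adjusted over the list alone). The median log2 fold change was −0.23, with 14 negative and 6 positive values. At an unadjusted p under 0.05, 11 were lower and 0 higher. DESeq2 and limma-voom each called 4 and robust empirical Bayes 6. The fit of protein-coding genes alone called 7 lower and 0 higher. The list passed camera at the preset correlation (adjusted p = 0.00275 over 23 lists with tested genes), but not with an estimated correlation (adjusted p = 0.800) or with fry (adjusted p = 0.0922). EREG changed by −0.59 ± 0.04 (SE, adjusted p = 1.95e-06), AREG by −0.88 ± 0.08 (4.37e-05), DUSP5, a nuclear ERK phosphatase, by −0.73 ± 0.07 (4.85e-05), and EPHA2, a receptor tyrosine kinase, by −0.45 ± 0.07 (0.00243). KLF6, a zinc-finger transcription factor, also fell, by 0.44 on the log2 scale (adjusted p = 0.0395), and in these 5 genes both knockout-labelled libraries lay below both controls. DUSP6, a cytoplasmic ERK phosphatase, had −0.33 ± 0.11, ETV5 −0.35 ± 0.10 and FOS −0.15 ± 0.08, while the immediate early gene EGR1 stood at 0.08 ± 0.06 and CCND1, cyclin D1, at 0.04 ± 0.06, none past the threshold. EREG, AREG and DUSP5 passed with any 1 library left out, EPHA2 lost its call without knockout-labelled replicate 1 (adjusted p = 0.0560) or 2 (0.0806), and KLF6 without any of the 4 (0.0647 to 0.282). ETV5 passed without control replicate 1 (−0.47, adjusted p = 0.00673). The EREG fall came from its main transcript (log2 ratio −0.61, against −0.02 over the rest), while both AREG transcripts were lower (−0.92 and −0.46).

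**Figure D2:**
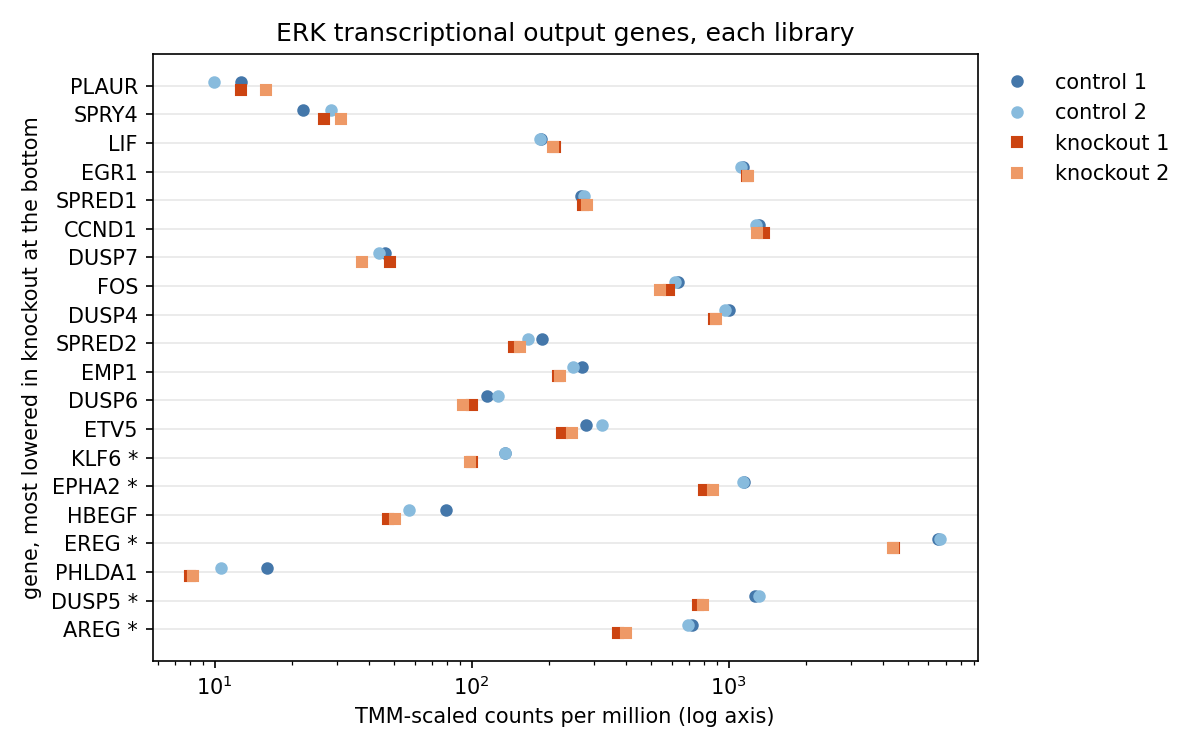
TMM-scaled CPM (log axis) of the 20 tested ERK transcriptional output genes in each library, with circles for controls and squares for knockout-labelled libraries, and an asterisk beside genes past adjusted p = 0.05. EREG sits near 6590 in controls and 4392 in knockout-labelled libraries, and AREG near 709 and 385, while CCND1 and EGR1 lie close together.

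The components of the MAPK/ERK pathway itself showed no call. Among 28 tested genes, from receptors to kinases, 0 passed over all genes and 0 when adjusted over the list alone, with a median of −0.10 and camera adjusted p = 0.370. EGFR had −0.25 ± 0.09, the ERK-activated kinase gene RPS6KA5 −0.52 ± 0.16 and RRAS −0.44 ± 0.16, and these were among 6 with an unadjusted p under 0.05 in edgeR, all lower. DESeq2 and limma-voom called 0 and robust empirical Bayes 2. BRAF (−0.10 ± 0.09) and PTPN11 (0.00 ± 0.07) differed little. When protein-coding genes were fitted alone, 2 of 27 passed, EGFR (adjusted p = 0.0249) and RPS6KA5 (0.0402), both lower. With all classes RPS6KA5 passed without control replicate 2 (−0.65, adjusted p = 0.0354).

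Cytosolic ribosomal protein genes, as a list, passed camera upward and cholesterol synthesis genes downward at the preset correlation, and neither passed with an estimated correlation (adjusted p = 0.800 for both) or with fry (0.0922 and 0.101). Of 69 tested ribosomal protein genes, 47 had a positive and 22 a negative log2 fold change, with a median of 0.19, and RPL6 alone passed (0.48 ± 0.11, adjusted p = 0.0337; 0 when adjusted over the list alone). RPLP1 had 0.57 ± 0.15 and RPS3A 0.63 ± 0.18 without passing. At an unadjusted p under 0.05, 16 were higher and 2 lower. DESeq2 and limma-voom called 0 and robust empirical Bayes 4. The fit of protein-coding genes alone called 7, 6 higher and 1 lower, with RPLP1 and RPS3A among those higher. The list's camera adjusted p was 0.00854 at the preset correlation. It was 0.113 without control replicate 1 and 0.0935, with a median of 0.11, without knockout-labelled replicate 2. RPL6 lost its call whichever of the 4 libraries was left out (adjusted p from 0.0675 to 0.270). Ribosomal protein genes have many pseudogenes, and RPL6 itself held 124 to 184 counts per library, so these values are uncertain. In cholesterol synthesis, 0 of 10 tested genes passed (0 over the list alone), 8 were negative and the median was −0.36, with STARD4 at −0.79 ± 0.24 and SQLE, which encodes squalene epoxidase, at −0.85 ± 0.37 (−0.23 without control replicate 2, and −1.31 with adjusted p = 0.00774 without control replicate 1). Its camera adjusted p was 0.0489, and 0.0514 under RLE scaling, 0.118 with no filter, 0.1102 without control replicate 2 and 0.102, with a median of −0.23, without knockout-labelled replicate 2. At an unadjusted p under 0.05, 4 of the 10 were lower, and DESeq2 and limma-voom called 0, robust empirical Bayes 1 and the fit of protein-coding genes alone 2.

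Stress-response lists moved in parts only. Of 20 tested targets of ATF4, the transcription factor of the integrated stress response, ATF3 (−1.37 ± 0.13) and the cystine transporter gene SLC7A11 (−0.31 ± 0.06) fell and VEGFA rose (0.87 ± 0.18), while 17 did not pass; 3 were higher and 3 lower when adjusted over the list alone. In the unfolded protein response list 1 of 17 fell, HSPA5, the ER chaperone BiP (−0.17 ± 0.04; 3 lower over the list alone). GDF15, a stress-induced cytokine, was the only 1 of 18 p53 targets to pass, at −0.52 ± 0.07 (1 lower over the list alone). PMAIP1, the pro-apoptotic gene for NOXA, fell among 13 apoptosis regulators (−0.63 ± 0.15; 2 lower over the list alone). Camera adjusted p was 0.995 for ATF4 targets, 0.439 for the unfolded protein response, 0.835 for p53 targets and 0.439 for apoptosis regulators. In the same order DESeq2 called 2, 0, 1 and 0 genes and limma-voom 4, 2, 1 and 0. Robust empirical Bayes and the fit of protein-coding genes alone each called 6, 3, 1 and 2. In that last fit the 3 unfolded protein response genes were HSPA5, ATF6 and DNAJB9, all lower. ATF3 passed with any 1 library left out; without knockout-labelled replicate 2 the other genes that moved had adjusted p from 0.0864 to 0.334, and without knockout-labelled replicate 1 SLC7A11, VEGFA, HSPA5 and PMAIP1 had 0.0861 to 0.221. VEGFA (0.0601) and PMAIP1 (0.0628) also missed the threshold without control replicate 1.

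Cell-cycle and translation lists held few changes. CENPF, a kinetochore protein gene (−0.40 ± 0.06), and TOP2A, DNA topoisomerase II alpha (−0.35 ± 0.07), fell among 9 tested G2/M genes (3 lower over the list alone). Of 16 G1/S and replication genes 0 passed, by either adjustment. Among 29 translation factors, EIF1, which takes part in start codon selection, fell (−0.58 ± 0.10) and EIF4B, a helicase cofactor, rose (0.41 ± 0.09), with 2 higher and 3 lower over the list alone. EPRS (−0.33 ± 0.08) and AARS (−0.23 ± 0.06) fell among 18 aminoacyl-tRNA synthetase genes (2 lower over the list alone). No member passed, by either adjustment, among 14 genes of m1A and tRNA methylation, where YTHDC1, an RNA methylation reader gene, had 0.67 ± 0.25, or among 29 mitochondrial ribosomal protein genes. At an unadjusted p under 0.05 there were 3 of these m1A and tRNA methylation genes, 2 G1/S genes and 2 mitochondrial ribosomal protein genes, and DESeq2, limma-voom and robust empirical Bayes called 0 in each of these lists. When protein-coding genes were fitted alone, 1 G1/S gene passed, CDT1, a replication licensing factor gene (0.39 ± 0.14, adjusted p = 0.04999), and 0 in the other 2 lists. Camera adjusted p was 0.439 for G2/M, 0.659 for G1/S, 0.969 for translation factors, 0.835 for synthetases, 0.439 for m1A machinery and 0.659 for mitochondrial ribosomal proteins. Without knockout-labelled replicate 2 the 6 genes that passed here had adjusted p from 0.132 to 0.347, without knockout-labelled replicate 1 all but CENPF had 0.0786 to 0.233, and without control replicate 2 EIF4B had 0.0693 and EPRS 0.0864.

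Metabolic and differentiation lists were also mixed. VEGFA and SLC2A1, the glucose transporter GLUT1 (0.50 ± 0.11), rose among 17 glycolysis and hypoxia genes (2 higher over the list alone), whereas EGLN3, another hypoxia-induced gene, had −1.14 ± 0.37 and PGK1 −0.25 ± 0.09 without passing. NDUFA10, a complex I subunit gene, rose among 24 nuclear-encoded oxidative phosphorylation genes (0.47 ± 0.11; 1 over the list alone). SOX9, a progenitor-cell transcription factor, rose (0.49 ± 0.08) and BMP4, a secreted morphogen, fell (−0.76 ± 0.18) among 10 WNT targets (1 and 1 over the list alone). No gene passed among 9 epithelial-mesenchymal transition genes, 9 interferon response genes and 2 intestinal markers, CA2 and CDX2 (each list 1 lower over the list alone), or for COL1A1, the 1 tested marker of other cell types (0 over the list alone). At an unadjusted p under 0.05 there were 2, 2, 1 and 0 genes in these lists, and DESeq2 and limma-voom called 0. Robust empirical Bayes and the fit of protein-coding genes alone each called 1 epithelial-mesenchymal transition gene, 1 interferon response gene and 0 in the other 2 lists. Camera adjusted p was 0.835, 0.370, 0.659, 0.835, 0.316, 0.439 and 0.835 for the lists in this order. Without knockout-labelled replicate 2 the adjusted p of SLC2A1, NDUFA10, SOX9 and BMP4 ranged from 0.0966 to 0.347, and without replicate 1 from 0.0743 to 0.176. Without control replicate 1, SLC2A1 had 0.122, NDUFA10 0.177 and BMP4 0.0763, and BMP4 had 0.0660 without control replicate 2.

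The median, the mean and the camera direction of a list differed in sign in 6 lists: p53 targets (0.04, −0.02, down), ATF4 targets (−0.00, 0.03, down), translation factors (−0.00, 0.07, up), glycolysis and hypoxia (−0.08, −0.01, up), replication-dependent histones (−0.04, −0.10, up) and the RNA quality list (−0.07, −0.02, up). With 1 library left out the median was −0.01 and −0.02 for p53 targets without knockout-labelled replicates 1 and 2 and 0.04 for ATF4 targets without control replicate 1. It was 0.02 and 0.01 for glycolysis and hypoxia without control replicate 2 and knockout-labelled replicate 1, and 0.00351 to 0.0445 for translation factors without any 1 of the 4. Mitochondrially encoded genes had no symbol in the table, so that list was not tested.

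**Figure D3:**
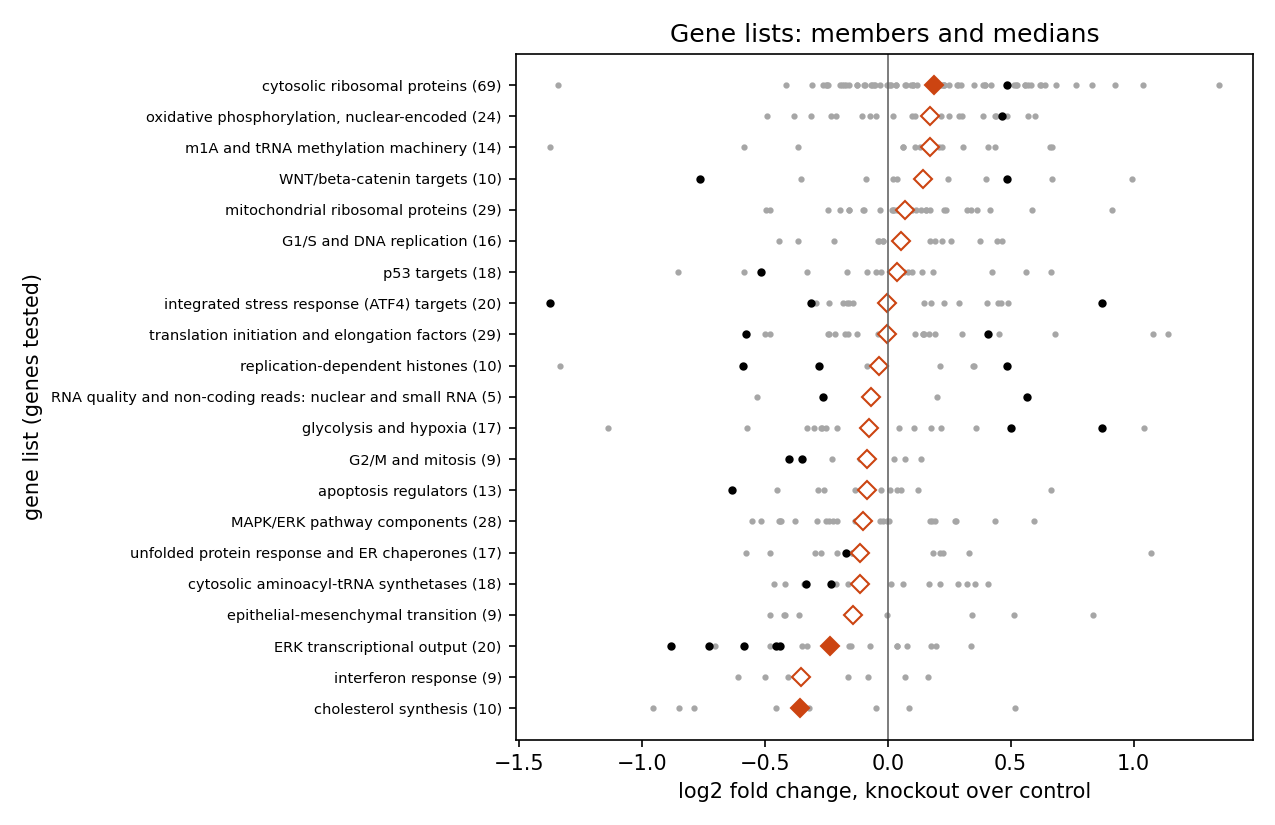
Log2 fold change, knockout-labelled over control, of the tested members of each gene list with at least 5 tested genes (grey points, black where adjusted p is under 0.05), and each list's median (diamond, filled where camera adjusted p at the preset correlation is under 0.05). Filled diamonds stand at 0.19 for ribosomal proteins, −0.23 for ERK output and −0.36 for cholesterol synthesis.

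RNY4, a Y RNA, rose from 144 ± 13.4 to 694 ± 10.7 CPM (2.27 ± 0.09 on the log2 scale). The U5 spliceosomal RNAs RNU5A-1 and RNU5B-1 rose by 1.53 ± 0.05 and 1.17 ± 0.05, and the vault RNA VTRNA1-2 by 1.39 ± 0.06. These rises did not extend to all Y and vault RNAs, where 1 of 3 tested genes passed in each family. RNY3 had 0.73 ± 0.27 and the more abundant RNY1 −0.14 ± 0.07. VTRNA1-1 had 0.03 ± 0.09 and VTRNA1-3 −0.29 ± 0.10. MIR148A rose by 1.38 ± 0.19 (0.91 without knockout-labelled replicate 2) and MIRLET7F2 by 1.12 ± 0.25 on the log2 scale (0.65 without that library). MIR146B rose from 164 ± 69.9 to 378 ± 55.0 CPM. The microRNA share was also higher in the knockout-labelled libraries. MIR148A itself held 0.748% and 0.517% of counts in controls, against 1.27% and 2.20% in knockout-labelled libraries. Of 113 tested microRNAs, 6 passed higher and 5 lower, with a median log2 fold change of 0.07. In the list of nuclear and small RNAs that read on RNA quality, 7SL RNA (RN7SL1) rose by 0.57 ± 0.05 and the nuclear lncRNA MALAT1 fell by 0.26 on the log2 scale, with 3 of 5 not past (2 higher and 2 lower over the list alone; camera adjusted p = 0.926). SNORD121A passed upward through 1 library (58 and 53 counts in controls, 61 and 3949 in knockout-labelled libraries; log2 fold change 0.14 and adjusted p = 0.813 without knockout-labelled replicate 2). SNORD19C passed downward (−2.28 ± 0.53) with 8473 of its control counts in control replicate 2; its log2 fold change was −0.48 without that library, and it lost its call without knockout-labelled replicate 1 (0.243) or 2 (0.409). RNY4, RNU5A-1, RNU5B-1, VTRNA1-2, MIR148A and RN7SL1 passed with any 1 library left out. Without knockout-labelled replicate 2, MIR146B had adjusted p = 0.267, MIRLET7F2 0.355 and MALAT1 0.112, and MALAT1 had 0.0747 without replicate 1.

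Several pseudogenes had counts in both controls and almost none in the knockout-labelled libraries. RNU6-35P, a U6 pseudogene, had 1288 and 1272 counts in controls and 1 and 0 in knockout-labelled libraries, a ratio of control over knockout-labelled of 2450 (95% counting interval 439 to 96825). The 5S rRNA pseudogene RNA5SP372 had 746 against 1 counts summed over each group, a ratio of 714 (128 to 28242), and AC074101.1 had 216 against 2, a ratio of 103 (28.3 to 859). RNU6-972P, with 131 counts in controls and 0 in knockout-labelled libraries, was at least 41.8-fold lower against a floor of 3 counts over the group. RNA5SP131 fell by 4.42 ± 0.29 on the log2 scale and AC132825.1 by 1.42 ± 0.09. These 6 features passed with any 1 library left out. RNU2-23P (−1.79 ± 0.36), RNA5SP358 (−1.57 ± 0.27) and RN7SL49P (−1.40 ± 0.27) also fell, and the 5.8S rRNA pseudogene RNA5-8SP6 rose (1.19 ± 0.26). These 4 had adjusted p from 0.0945 to 0.246 without knockout-labelled replicate 2, and RN7SL49P (0.142) and RNA5-8SP6 (0.249) lost their calls without replicate 1. All of these features share sequence with multicopy or parent genes, or have no class in the gene table, and are uncertain.

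By the rule fixed before the data were examined, LETMD1 (1.29 ± 0.25), the histone H3 gene HIST2H3D (1.15 ± 0.23) and GPN2 (1.05 ± 0.23) were named upward and the transcription factor gene CREB5 (−1.54 ± 0.32) and ARL14EPL (−1.51 ± 0.23) downward. The same rule within protein-coding genes, chosen after the values were seen, added EZH2, the Polycomb methyltransferase (57.8 ± 0.645 to 28.6 ± 0.811 CPM, −1.01 ± 0.19; its copy EZH2P1 had 23 control and 2 knockout-labelled counts, so shared reads make it uncertain), the nuclear receptor NR4A1 (−0.88 ± 0.17) and CCN1, a matricellular protein gene (−0.84 ± 0.12), to those that fell. It also added YIPF5, ST6GALNAC4, HELZ2, B3GNT3, FAM234B and the histone gene HIST1H4I, from −1.29 to −0.82, besides ATF3 and AREG. Upward it added MAP1LC3B (0.99 ± 0.05), ATRX, a chromatin remodeller gene (0.87 ± 0.10), NASP, a histone chaperone gene (0.82 ± 0.11), the copper chaperone gene ATOX1 (1.01 ± 0.21), ALDH2, aldehyde dehydrogenase 2 (0.98 ± 0.24), TMEM107, CDKN2AIPNL, KNOP1 and VEGFA. The MAP1LC3B rise came from transcript ENST00000650688 (log2 ratio 1.05), against −0.52 over the gene's remaining transcripts. For ATRX the split was 1.40 for ENST00000623706 and −0.23 for the rest, for NR4A1 −1.13 for ENST00000550557 and 0.20, and for BMP4 −1.13 and 0.18. When a knockout-labelled library is left out, the spread rests on the control pair alone. Calls lost that way do not by themselves show a changed fold. Of the 67 named genes of all classes past the threshold, 19 passed with any 1 library left out, and 11, 6, 38 and 48 lost their call without control replicates 1 and 2 and knockout-labelled replicates 1 and 2. In this paragraph MAP1LC3B, ATRX, ATF3 and AREG were among the 19, while CCN1 (adjusted p = 0.113), CREB5 (0.254) and NASP (0.106) lost their calls without knockout-labelled replicate 2. The other genes named here lost theirs without either knockout-labelled replicate, with adjusted p from 0.0676 for ARL14EPL to 0.262 for KNOP1 without replicate 1 and from 0.103 for ARL14EPL to 0.334 for VEGFA without replicate 2. Without control replicate 1 the adjusted p was 0.0601 for VEGFA, 0.0938 for B3GNT3, 0.161 for ALDH2, 0.0671 for TMEM107, 0.0949 for KNOP1 and 0.0763 for BMP4. Without control replicate 2 it was 0.0677 for ATOX1, 0.0532 for FAM234B and 0.0660 for BMP4.

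The authors' deposited table marks 71 transcripts up and 119 down. In the authors' deposited table these marks equal an unadjusted p under 0.05 with an absolute log2 fold change over 1 in all 66740 transcripts, and 30 marked transcripts have an adjusted p under 0.05. By the authors' deposited adjusted p, 144 of 14755 transcripts pass, 29 higher and 115 lower.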

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

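Transcripts as features and the settings that join protein-coding genes with another change were chosen after seeing the data. The 381 calls (116 higher, 265 lower) numbered 366 under RLE scaling, all of them shared, 369 under upper-quartile scaling, 397 with the stricter filter, 347 with limma-voom and 399 with transcripts as features. With no filter there were 279, of which 61 were higher. DESeq2 called 238 (55 higher), all shared with edgeR; robust empirical Bayes 736 (226 higher, 510 lower); protein-coding genes alone 626 (207 higher, 419 lower); and the authors' adjusted p 144 transcripts (29 higher, 115 lower). The cause of these differences was not tested, except that the protein-coding fit had a smaller estimated spread. Leaving out 1 library gave 52 to 472 calls (15 to 157 higher, 37 to 322 lower), with the fewest without knockout-labelled replicate 2 and 124 without replicate 1, where the lone library is assumed to vary like the control pair. The replicate numbers share only a number: same-numbered libraries did not deviate together (r = 0.00303 across 3358 genes, which are not independent replicates). With the number as a block 442 genes were called (144 higher, 298 lower), and 3 lists. TRMT61A ranged from −0.14 to 1.24 on the log2 scale with 1 library left out, and passed the threshold in no fit that gave it an adjusted p, which DESeq2 did not; the fold reversed without control replicate 1. Of the 3 lists called, 1 to 3 passed with 1 library left out, 0 with an estimated correlation and 0 with fry, where the medians stay at −0.23 for ERK output, 0.19 for ribosomal proteins and −0.36 for cholesterol synthesis. ERK output passed in the other settings run (median −0.25 to −0.16 with 1 library left out). Ribosomal proteins had 0.11 to 0.16 there and lost their call without control replicate 1 or knockout-labelled replicate 2. Cholesterol synthesis had −0.48 to −0.23 there and also lost its call under RLE scaling (−0.36), with no filter (−0.38), with protein-coding genes only (−0.35) and with those without control replicate 2 (−0.28). Among 148 other results over all settings, 1664 values kept their direction and side of the threshold, 151 lost and 65 gained a call, and 22 changed sign, all without a call. They were 2 genes, MKI67 (−0.29 to 0.12 with 1 library left out) and CDX2 (−0.64 to 0.16), and medians of 7 lists, for which the cause was not tested. With 1 library left out the medians ranged from −0.0164 to 0.0858 for p53 targets, −0.0407 to 0.0371 for ATF4 targets, 0.00351 to 0.0445 for translation factors, −0.181 to 0.0160 for glycolysis and hypoxia, −0.181 to 0.0326 for epithelial-mesenchymal transition and −0.281 to 0.0748 for apoptosis regulators. With no filter they were −0.0367 for G1/S genes and 0.126 for glycolysis and hypoxia. With protein-coding genes only they were 0.00653 for ATF4 targets and 0.00525 for translation factors. With those genes and without control replicate 2 they were 0.00969 for translation factors, 0.0630 for glycolysis and hypoxia, 0.0248 for epithelial-mesenchymal transition and 0.0808 for apoptosis regulators. In data simulated with these library sizes and 1 dispersion for all genes, 7.46% of genes changed 1.5-fold were recovered, but depth was not varied. The few TRMT61A reads left a rate ratio between 0.611 and 3.43 by counting error alone.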

Other observations

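Tests on the near-absent pseudogenes, on control replicate 2 in the ERK list and on snoRNA fragment length, and the families below, were chosen after the results were seen; the other 3 tests were written before theirs. All 4 tested U5 spliceosomal RNA genes rose under TMM, RLE and upper-quartile scaling, from 0.48 for RNU5F-1 to 1.53 for RNU5A-1. The U1 variant RNVU1-7 (−0.60 ± 0.04) and RNU4-1 of U4 (−0.79 ± 0.08) fell, and the 7SL genes RN7SL1 and RN7SL3 rose (0.57 ± 0.05 and 0.46 ± 0.08). The U1 and U4 falls did not hold for their families. Of 5 tested U1 genes 1 was called lower and 0 higher, with values from −0.67 to 1.03. Of 2 tested U4 genes, RNU4-2 had 0.12 ± 0.07 without passing. Histone genes went both ways, and no difference between histone types was tested. In the replication-dependent histone list fixed beforehand, 1 of 10 genes rose and 2 fell (4 and 3 over the list alone; camera adjusted p = 0.969). HIST1H4C fell (1914 ± 38.2 to 1274 ± 46.8 CPM), as did H1F0 (−0.54 ± 0.05) and H1FX (−0.79 ± 0.11), and HIST2H2BE (0.72 ± 0.07) and HIST1H2BO (0.77 ± 0.09) rose. HIST1H4A fell (−0.28 ± 0.07) and HIST1H2BK rose (0.48 ± 0.12), but both lost their calls without knockout-labelled replicate 1 (adjusted p = 0.199 and 0.175) or 2 (0.261 and 0.353), and HIST1H2BK without control replicate 1 (0.29 on the log2 scale, adjusted p = 0.284). HIST1H4B (0.21 ± 0.06) and HIST1H2BD (−1.33 ± 0.41) went against these members of their types without passing, and passed when protein-coding genes were fitted alone (adjusted p = 5.97e-08 and 0.00495). HIST1H2BD passed there although its controls spread widely, at 23.9 ± 12.1 CPM. With all classes HIST1H4B also passed without control replicate 2 (0.25, adjusted p = 0.000550) and HIST1H2BD without control replicate 1 (−1.79, adjusted p = 0.000397), while HIST1H2BD had −0.71 without control replicate 2. RNU5A-1, RNU5B-1, RNVU1-7, RNU4-1, RN7SL1, HIST1H4C, H1F0, HIST2H2BE and HIST1H2BO passed with any 1 library left out. RNU5D-1 (adjusted p = 0.0571), RNU5F-1 (0.104), RN7SL3 (0.182) and H1FX (0.113) lost their calls without knockout-labelled replicate 2, and RNU5F-1 (0.0532) without replicate 1. Near-identical copies make single members uncertain.

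Other protein-coding genes with small adjusted p in edgeR, picked after their values were seen, were mostly lower. They included AHNAK, a giant scaffold protein gene (6217 ± 3.49 to 4600 ± 71.7 CPM), FTL, ferritin light chain (1610 ± 3.99 to 1014 ± 20.1), TOP1, DNA topoisomerase I (1866 ± 7.65 to 1236 ± 26.0), and ERRFI1, a feedback inhibitor of EGFR (3964 ± 77.0 to 2922 ± 35.7). These 4 passed with any 1 library left out. DKK1, a WNT antagonist gene (−0.68 ± 0.08), and SCD, stearoyl-CoA desaturase (−0.33 ± 0.05), also fell, with adjusted p of 0.0571 and 0.106 without knockout-labelled replicate 2.

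In all, 16 features past the threshold had counts in controls and 3 or fewer over the knockout-labelled libraries, against 2 in the opposite direction. Of the 16, 12 were pseudogenes, or 75%, against 5.25% of the other tested features (Fisher's exact test, two-sided, p = 7.415e-13, a test chosen after the features were seen, so it describes them and supports no explanation), and 1, YPEL5, was a protein-coding gene. A mapping or filtering change that lowered pseudogenes in general is argued against by the other 520 tested pseudogenes, with a median log2 fold change of 0.04526 (95% bootstrap interval −0.01 to 0.11). A median cannot see a change in a part of the class. Of all 532 tested pseudogenes 39 were called lower and 13 higher, against 175 and 67 of 7378 protein-coding genes. Loss of 1 chromosome segment is argued against because the 13 features placed by symbol lie on 10 chromosomes. What stays open is a mapping or filtering change in a part of the pseudogenes, reads shared with parent genes, a sequence variant that differs between the cell populations, and an effect of the knockout. None of these could be tested without reads.

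The ERK output list may be lower for a technical reason, and 2 were tested. Its median lay at percentile 1.37 of 10000 random lists matched on expression, whose medians centred on −0.08, so an abundance trend does not account for all of it. The ERK list was not singled out by this check. Ribosomal proteins lay at percentile 99.99 and cholesterol synthesis at 0.21 of their own matched lists. With protein-coding genes only and without control replicate 2, the ERK list's median was −0.2396, so the small RNA content of that library is not the cause. An effect of TRMT61A on ERK output remains a hypothesis. The list did not pass camera with an estimated correlation, or fry. That estimate was −0.0135, below the preset 0.01, so the lost call does not show that members vary together. Cholesterol synthesis lost its call too, at an estimate of −0.0552. With an estimated correlation, which must be drawn from 4 libraries, 0 lists passed, so these losses decide little about any list. The few TRMT61A reads do not check the label. A clonal or culture difference between the 2 groups could give the same pattern and was not tested.

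Control replicate 2 held more snoRNA than control replicate 1. Without SNORD101, SNORD104 and SNORD69 the shares still differed 1.657-fold, so those 3 genes are not the whole cause. A different range of fragment lengths stays open, since its tests went apart. The median log2 ratio of counts, control replicate 2 over 1, was 0.118 for 53 C/D box (SNORD) snoRNAs. It was 0.0098 for 45 longer H/ACA box (SNORA) snoRNAs, a difference of 0.1086. For microRNAs, the shortest class, it was −0.60, against 0.02 for protein-coding genes. The typical snoRNA thus lay near the protein-coding median, so the excess sat in a part of the snoRNAs and not across the class. No biological explanation was tested, since both libraries belong to 1 group.

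A further hypothesis came from CCN1 and AXL, which are targets of the YAP/TEAD transcription factors and were lower (−0.84 ± 0.12 and −0.77 ± 0.10; adjusted p = 0.113 and 0.0887 without knockout-labelled replicate 2). Among the 13 other tested genes of a list of such targets, 1 fell (PTPN14, −0.41 ± 0.09; adjusted p from 0.0522 to 0.190 without control replicate 2 or either knockout-labelled replicate), 7 were negative and the median was −0.04. Camera gave that group p = 0.3402 at the preset correlation and 0.419 with an estimated one. These data do not decide whether the group is lower.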
